A study of Homo sapiens with 12 samples.

How the data were processed

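Total RNA of H7 human embryonic stem cells in directed cardiomyocyte differentiation was extracted with Trizol and made into Illumina libraries from 1 ug each, and mRNA profiles were read on a HiSeq X10 sequencer, per the labels' protocols. The labels put 12 libraries into 6 groups of 2 (wild type and E2A knockout at days 3, 7 and 15). Replicates carry the numbers 1 and 2, and nothing in the labels says whether they came from separate cultures.

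The deposited values are FPKM per gene symbol, 1 file per library. The unit is not stated in the labels and was inferred from the values: their sums differ between libraries (577716 to 734958), and the low values of a gene step in a way that depends on its length. Per the submitters' processing notes BWA was used and the genome was hg38 (GRCh38). The program that computed the values, its annotation, the strand setting and the treatment of reads with several placements are not given in the sources used here, so overlapping genes, antisense genes and near-identical copies remain uncertain. All 17096 listed genes are above 0 in all 12 libraries, and TBXT, SHOX2 and TBX18, looked up under current and older symbols, were not analysed here. Of the symbols, 22 had been turned into dates and 9 occur more than once (18 rows), and none of these is named. Gene places are those of GENCODE release 29 on GRCh38, where 15098 symbols (88.3%) were found, with 1-based positions.

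Depth was estimated from 863 genes with a single annotated transcript of at least 1500 bases, by the fragment count that brings their low values closest to whole fragments. This gave 6800000 to 11600000 fragments per library, with 58.6% to 78.3% of the low values (17 to 46 genes per library) within 0.1 of a whole number. As this share was not near all, no fragment counts were rebuilt and no count model was used. These depths are estimates, and no counting intervals were drawn from them. No pair of replicates held identical values.

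Each test was limma (version 3.58.1 in R 4.3.3) with its trend option on log2(FPKM + 1), on genes with at least 1 FPKM in at least 2 libraries, which left out 801 and kept 16295. A model of 6 group means on all 12 libraries (6 residual degrees of freedom) gave 9 contrasts: labelled knockout against wild type at each day, day 7 against day 3 and day 15 against day 7 within each genotype, and the difference of the genotype effect between neighbouring days. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes tested, with 0.05 as the threshold.

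The contrasts, the alternatives, 38 gene lists and the rule for named genes were fixed before the data were examined. That rule names a set of E protein, mesoderm and cardiac genes whatever they show, the 6 largest rises and 6 largest falls of each genotype contrast with a mean of at least 5 FPKM in the higher group and both labelled knockout libraries outside the wild-type range, the 5 largest of each in other contrasts at the same level, and up to 4 members of each list past the threshold with the smallest adjusted p. LINC01021 is one of those falls. Some results, 1 gene list among them, are not reported here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 37 lists with at least 3 members tested. At day 3, 1 list was higher and 13 lower, and 4 of these 14 calls held with an estimated correlation. At day 7, 4 were higher and 19 lower, and 11 held. At day 15, 3 were higher and 6 lower, and 1 held. Where no such p is given beside a passing list in the results, the call held. The fry test, which asks whether a list's genes move one way on balance and compares them with no other genes, also passed for all 14, 23 and 9 of these lists. As it passed for 29, 33 and 29 of the 37 lists at days 3, 7 and 15, this adds little to the camera calls. Some lists share members.

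The code was tested on simulated data drawn with a spread per gene taken from the real libraries and shared by all groups. With 100 genes changed by 1 on the log2 scale and 100 by 2, the comparison at day 3 (16172 genes run) recovered 85% and 100%, that at day 7 (16122) 81% and 99%, and that at day 15 (16139) 75% and 99%, and 3.1%, 6.2% and 7% of the calls were false. The changed genes were drawn from those at 5 FPKM or more in the wild type of that day. In the real data the libraries labelled knockout at day 15 varied more (pooled SD 0.323 on the log2 scale, against 0.208 to 0.267 in the other groups). The simulation lacks this, so its values for day 15 may be too favourable. On lists of 12 genes shifted by 0.6 at day 3, camera called 10 of 10, and it called 0 of 300 unshifted lists. Those lists held random genes with independent noise, and no other gene was changed. They therefore do not test the preset correlation on real lists, whose genes can vary together.

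Alternatives were median-ratio rescaling, no filter, a filter at 5 FPKM, a pseudocount of 0.1, limma without the trend, a fit on the compared groups alone, the replicate number as a block, and leaving out each library in turn. An overlap at changes of at least 1, a correlation over all genes, an estimated correlation and fry were run for the results they apply to. Scaling to the sum of nuclear genes was added after seeing that mitochondrially encoded transcripts held a share of FPKM that differed between groups. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.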

Results

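RNA of H7 cells, a human embryonic stem cell line, was sequenced at days 3, 7 and 15 of directed differentiation into cardiomyocytes. At each day a wild-type group and a group labelled as knockout of E2A were sampled with 2 libraries each, which gives 12 libraries in 6 groups. E2A is an older name of TCF3, which encodes a basic helix-loop-helix transcription factor of the E protein class. The values analysed are FPKM per gene for 17096 listed genes, all above 0 in all 12 libraries. TBXT, SHOX2 and TBX18 were not analysed here. The FPKM of a library summed to between 577716 and 734958, and the spacing of its low values corresponds to an estimated 6800000 to 11600000 fragments. Replicates correlated across genes at r between 0.973 and 0.990. Mitochondrially encoded transcripts held 16.9% and 15.7% of summed FPKM in the wild-type libraries at day 3, 8.5% and 8.1% at day 7, and 26.1% and 26.2% at day 15. In the libraries labelled knockout these shares were 18.8% and 17.4%, 20.2% and 18.5%, and 13.9% and 14.3%. The origin of the replicates is not stated, so the p-values measure only the spread between these samples, which may be technical.

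Changes are log2 changes of FPKM + 1, a scale that understates genes with low values, as labelled knockout minus wild type with the SE of limma, and levels are means ± SD in FPKM of n = 2 libraries. TCF3 (GRCh38 chromosome 19, 1609290 to 1652605, minus strand) was read first, in every library. At day 3 it stood at 179.5 and 148.9 FPKM in the wild-type libraries and at 145.9 and 148.1 FPKM in those labelled knockout, a log2 change of -0.15 (SE 0.19, adjusted p = 0.618 with limma). At day 7 the values were 135.2 and 138.0 against 179.9 and 172.1 FPKM (0.36, SE 0.19, adjusted p = 0.159), a change that passed in a fit on the libraries of that day alone (adjusted p = 0.0164) and when scaled to the sum of nuclear genes (0.569, adjusted p = 0.0235). At day 15 they were 74.4 and 98.2 against 169.7 and 108.3 FPKM, and TCF3 was higher in the libraries labelled knockout by 0.66 (SE 0.19, adjusted p = 0.0234). That last call ended without replicate 1 of the labelled knockout (0.34) and without wild-type replicate 1 (0.46), and in a fit on the libraries of that day alone (adjusted p = 0.0774). No fall in the mRNA of the targeted gene passed the test in any comparison of the genotypes, and the groups are called libraries labelled knockout throughout. Every direction drawn below rests on those labels. The position of the edit is not given in the labels, and protein was not measured. Of the related E proteins, TCF4 did not pass the test at any day (log2 changes of 0.34, 0.63 and 0.55). TCF12 stood at 45.8 ± 14.8 against 19.2 ± 2.35 FPKM at day 15 and was higher by 1.18 (SE 0.26, adjusted p = 0.00615), while its changes of 0.01 at day 3 and 0.37 at day 7 did not pass.

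**Figure D1:**
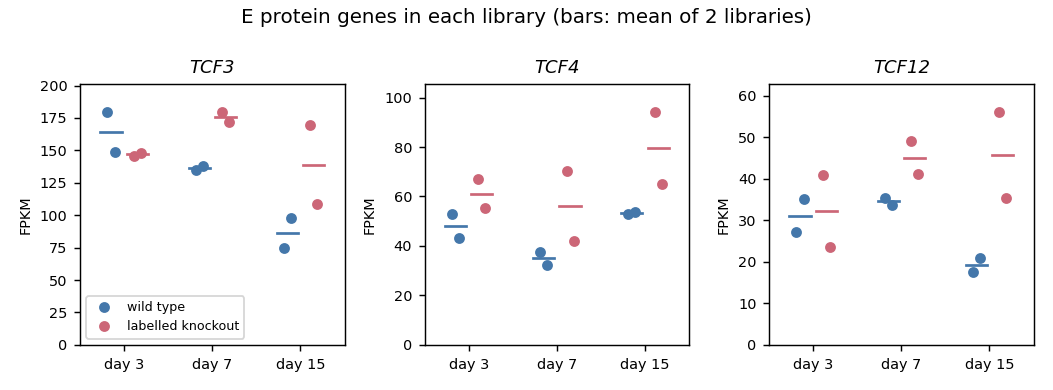
FPKM (vertical axis, linear, from 0) of TCF3, TCF4 and TCF12 in each of the 12 libraries by day, wild type in blue and labelled knockout in red, each point a library and each bar the mean of 2 libraries. TCF3 lies between 74.4 and 179.9 FPKM in all 12 libraries and is not lower in the libraries labelled knockout by the test at any day.

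The wild-type libraries give the course against which the genotypes were compared. From day 3 to day 7 MYH6, the atrial myosin heavy chain, rose from 0.154 ± 0.0404 to 1880 ± 51.3 FPKM, a log2 change of 10.67 (SE 0.13). TNNT2, cardiac troponin T, rose by 9.11, and MYL7, the atrial myosin light chain, by 9.57. NKX2-5, a transcription factor of cardiac progenitors, rose by 6.05 and ISL1, a marker of second heart field progenitors, by 3.54. EOMES, a T-box factor of the primitive streak, fell by 5.82, and CER1, a secreted NODAL antagonist, fell by 6.84. All 16 measured sarcomere genes rose, also 16 adjusted over the list alone, with a mean of 5.93 (camera adjusted p = 1.08e-18). BMP pathway genes rose in 15 of 18 cases and fell in 1, or 16 and 1 adjusted over the list alone, with a mean of 1.59 (adjusted p = 1.16e-08). All 8 pluripotency genes fell, also 8 adjusted over the list alone (mean -1.92, adjusted p = 1.86e-06, and 0.0632 with an estimated correlation).

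Between days 7 and 15 the myosin heavy chains moved in opposite directions in the wild-type libraries. MYH7, the ventricular and slow skeletal myosin heavy chain, rose by 3.78 (SE 0.17), from 30.2 ± 1.31 to 429 ± 47.1 FPKM, while MYH6 fell to 667 ± 49.5 FPKM (adjusted p = 8.92e-06). INHBA, which encodes a subunit of activin, rose by 4.69, and DLK1, a non-canonical NOTCH ligand, fell from 451 ± 21.8 to 13.1 ± 1.3 FPKM. Glycolysis and hypoxia genes fell in 12 of 14 cases, also 12 adjusted over the list alone (mean -1.35, adjusted p = 1.18e-06, and 0.154 with an estimated correlation). All 11 mitochondrially encoded transcripts of the fixed list rose, also 11 adjusted over the list alone (mean 2.06, adjusted p = 5.08e-09, and 0.154 with an estimated correlation). MYH6 and MYH7 are neighbours on chromosome 14 with similar sequences, and reads shared between them cannot be placed here because the authors' counting is not described in the sources used here. The same holds for actin genes and for mitochondrially encoded genes with nuclear copies. Of 16295 genes tested, 7128 changed between days 3 and 7 in the wild type (3442 higher and 3686 lower), and 8517 between days 7 and 15 (4149 higher and 4368 lower).

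At day 3 the question was which genes differed between the genotypes at the stage the labels call cardiac mesoderm. Genes of the primitive streak and mesendoderm were lower in the libraries labelled knockout. MIXL1, a homeobox factor of the streak, fell by 1.97 (SE 0.22) from 385 ± 0.691 FPKM, EOMES stood at 50.6 ± 2.41 against 185 ± 4.42 FPKM (-1.85, SE 0.18), and GSC, a factor of the organizer, at 7.76 ± 0.613 against 24.9 ± 1.79 FPKM (-1.56, SE 0.18). Of the 11 measured members of this list 10 fell, or 11 adjusted over the list alone, with a mean of -1.51 (camera adjusted p = 1.23e-08). Its adjusted p was 0.0777 with an estimated correlation. LEFTY2, a feedback inhibitor of NODAL signalling, fell by 3.05 (5.04 ± 0.727 against 48.9 ± 1.11 FPKM), and NODAL itself fell by 1.69. MESP1, an early factor of cardiac mesoderm, stood at 4.6 ± 0.884 against 10.3 ± 1.55 FPKM, and its change of -1.02 (SE 0.35, adjusted p = 0.0599) did not pass.

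Other germ-layer and progenitor groups were lower at day 3 as well. Endoderm genes fell in 6 of 9 cases, also 6 adjusted over the list alone, with a mean of -1.22 (adjusted p = 7.66e-06), among them FOXA2 (-2.30, SE 0.14) and SOX17 (-1.68, SE 0.18), both regulators of definitive endoderm. In the cardiac mesoderm list GATA4, a zinc finger factor of heart and endoderm, fell by 1.67 and APLNR, the apelin receptor, by 1.70, while TMEM88, a WNT inhibitor of cardiac specification, rose from 6.2 ± 0.12 FPKM (adjusted p = 3.52e-04). That list had 6 lower and 2 higher members of 13, or 8 and 3 adjusted over the list alone (adjusted p = 0.0235, and 0.345 with an estimated correlation). Paraxial mesoderm genes fell in 5 of 9 cases, also 5 adjusted over the list alone, led by the NOTCH ligand DLL3 (-2.26, SE 0.20), with an adjusted p of 0.0215, and 0.162 with an estimated correlation. Cardiac transcription factors fell in 5 of 12 cases, or 5 lower and 1 higher adjusted over the list alone (adjusted p = 0.0174, and 0.339 with an estimated correlation). ISL1 fell by 1.25, NKX2-5 by 1.36 and TBX3, a T-box factor of the pacemaker lineage, by 1.51. HCN4, the main pacemaker channel, was higher by 0.55 (adjusted p = 0.0326), a call that ended without any 1 of the 4 libraries of that day (0.52 and 0.59 without labelled knockout replicates 1 and 2, 0.63 and 0.48 without wild-type replicates 1 and 2) and in a fit on that day alone. TNNT2, MYH6 and NPPA, the atrial natriuretic peptide, were near the floor at day 3, with adjusted p of 0.346, 0.235 and 0.124, and did not pass.

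Signalling groups moved in the same comparison. BMP pathway genes fell in 10 of 18 cases, or 10 lower and 1 higher adjusted over the list alone, with a mean of -0.81 (adjusted p = 4.49e-07). Among them ID1 fell by 1.46 (69.7 ± 5.63 against 194 ± 0.761 FPKM) and ID3 by 1.86 (35.3 ± 2.09 against 131 ± 4.73 FPKM); both are BMP-responsive and bind E proteins. WNT pathway genes fell in 11 of 16 cases and rose in 1, the same counts adjusted over the list alone (adjusted p = 0.00741, and 0.285 with an estimated correlation), with DKK1, a secreted WNT antagonist, lower by 1.66 and SFRP1, another, higher by 1.17. Cholesterol synthesis genes fell in 9 of 13 cases, or 11 adjusted over the list alone (mean -0.57, adjusted p = 1.67e-05). Immediate early genes fell in 5 of 12 cases, or 7 adjusted over the list alone, with FOS lower by 2.07 and EGR1 by 1.95 (adjusted p = 2.31e-04, and 0.162 with an estimated correlation). Amino acid and unfolded protein stress genes fell in 9 of 13 cases, or 10 adjusted over the list alone, among them HSPA5, an endoplasmic reticulum chaperone, by 0.88 (adjusted p = 3.16e-06, and 0.19 with an estimated correlation). Matrix genes fell in 5 of 9 cases, also 5 adjusted over the list alone, led by FN1, fibronectin (-1.78), with an adjusted p of 0.00741, and 0.216 with an estimated correlation. Epithelial genes fell in 6 of 12 cases, also 6 adjusted over the list alone, led by KRT18, a simple-epithelial keratin (-1.47), with an adjusted p of 0.0207, and 0.347 with an estimated correlation.

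The largest falls among the genes named by rule at day 3 were in 2 regulators of growth and survival. PHLDA3 (chromosome 1, 201464383 to 201469237), an inhibitor of AKT, stood at 0.381 ± 0.31 against 49.2 ± 3.26 FPKM (-5.20, SE 0.21, adjusted p = 1.2e-06). CDKN1A (chromosome 6, 36676460 to 36687339), the cyclin-dependent kinase inhibitor p21, stood at 0.437 ± 0.221 against 32.1 ± 5.44 FPKM (-4.53, SE 0.20). LINC01021, a long non-coding RNA, fell by 3.30.

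Single genes of neural character and the glycolysis list were higher at day 3. FEZF1, a forebrain zinc finger factor, rose from 0.784 ± 0.491 to 30.5 ± 2.52 FPKM (4.17, SE 0.21), SOX21, a neural HMG-box factor, by 3.50 (45.0 ± 0.299 against 3.1 ± 0.726 FPKM), and MAP2, a neuronal microtubule protein, by 3.42. SOX2, which marks both pluripotent and neural cells, rose by 2.15 (201 ± 11.2 against 44.6 ± 2.79 FPKM). PAPLN, which is not in the neural list, also rose, to 36.9 ± 3.66 from 1.61 ± 0.131 FPKM. The neural list as a whole had 3 higher and 2 lower members of 7, the same counts adjusted over the list alone, and did not pass (adjusted p = 0.523, with a mean of 0.28, a median of -0.18 and an upward test). In that list OTX2 stood lower, at 85.8 ± 5.31 against 163 ± 5.34 FPKM, and TUBB3 at 156 ± 10.9 against 220 ± 0.419 FPKM. The call of TUBB3 (-0.50) ended without labelled knockout replicate 1 (-0.43) or either wild-type replicate (-0.49 and -0.50). Glycolysis and hypoxia genes rose in 8 of 14 cases, or 9 adjusted over the list alone, with a mean of 0.70, led by HK2, a hexokinase, at 1.51 (SE 0.12) and PFKFB4, which makes a regulator of glycolysis, at 1.77 (adjusted p = 7.66e-06, and 0.162 with an estimated correlation). Mitochondrially encoded transcripts, at a mean of 0.02, did not pass (adjusted p = 0.872), with 2 higher and 1 lower of 11, the same counts adjusted over the list alone.

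In all, 3849 of 16295 genes changed at day 3, 1550 higher and 2299 lower, of which 1056 changed at least 2-fold on the log2(FPKM + 1) scale. Scaled to the sum of nuclear genes, 62.2% of the changed genes were higher in place of 40.3%, and the median change of all genes moved from -0.01 to 0.12. Leaving out a library left 2003 genes without wild-type replicate 1, 1990 without wild-type replicate 2, 2040 without labelled knockout replicate 1 and 2503 without labelled knockout replicate 2.

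At day 7 the comparison concerned cells on the way to beating cardiomyocytes, and genes of the contractile apparatus were lower in the libraries labelled knockout. MYH7 (chromosome 14, 23412738 to 23435718) stood at 0.593 ± 0.0596 against 30.2 ± 1.31 FPKM (-4.29, SE 0.17, adjusted p = 2.05e-07), MYH6 at 509 ± 65.2 against 1880 ± 51.3 FPKM (-1.89, SE 0.13) and TNNT2 at 210 ± 39.3 against 831 ± 29.6 FPKM (adjusted p = 5.19e-05). TNNC1, troponin C, fell by 3.43. Of 16 measured sarcomere genes 14 fell, or 15 adjusted over the list alone, with a mean of -2.18 (camera adjusted p = 6.64e-12). NPPA (chromosome 1, 11845709 to 11848345) showed the largest fall among the genes named by rule, at 2.49 ± 0.573 against 78.0 ± 5.75 FPKM (-4.51, SE 0.17, adjusted p = 1.48e-07).

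Calcium handling genes fell in 10 of 11 cases, also 10 adjusted over the list alone, with a mean of -1.31 (adjusted p = 6.56e-07), among them SLC8A1, the sodium-calcium exchanger, by 2.31 and JPH2, junctophilin, by 1.66. Cardiac transcription factors fell in 10 of 12 cases, also 10 adjusted over the list alone, with NKX2-5 at 43.7 ± 1.61 against 213 ± 12.9 FPKM (-2.26, SE 0.19) and HAND1, a left-ventricular factor, lower by 2.64 (adjusted p = 3.31e-06, and 0.0678 with an estimated correlation). Ventricular genes fell in 6 of 7 cases, also 6 adjusted over the list alone (mean -1.41, adjusted p = 1.6e-04). Working chamber genes fell in 6 of 10 cases and rose in 1, or 7 and 1 adjusted over the list alone, led by NPPA and the muscle creatine kinase CKM (-4.04), with an adjusted p of 2.29e-04, and 0.0659 with an estimated correlation. In the sinoatrial node list ISL1 fell by 1.52, TBX3 by 1.17 and HCN4 by 1.22 (5.19 ± 0.636 against 13.4 ± 0.293 FPKM). That list had 6 lower and 2 higher members of 14, the same counts adjusted over the list alone, and did not pass (adjusted p = 0.0705). Atrial genes, 4 lower and 2 higher of 10, the same counts adjusted over the list alone, did not pass either (adjusted p = 0.138). MYL4 fell there by 2.40 and NR2F1, an orphan nuclear receptor of atrial and neural cells, rose by 2.92.

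**Figure D2:**
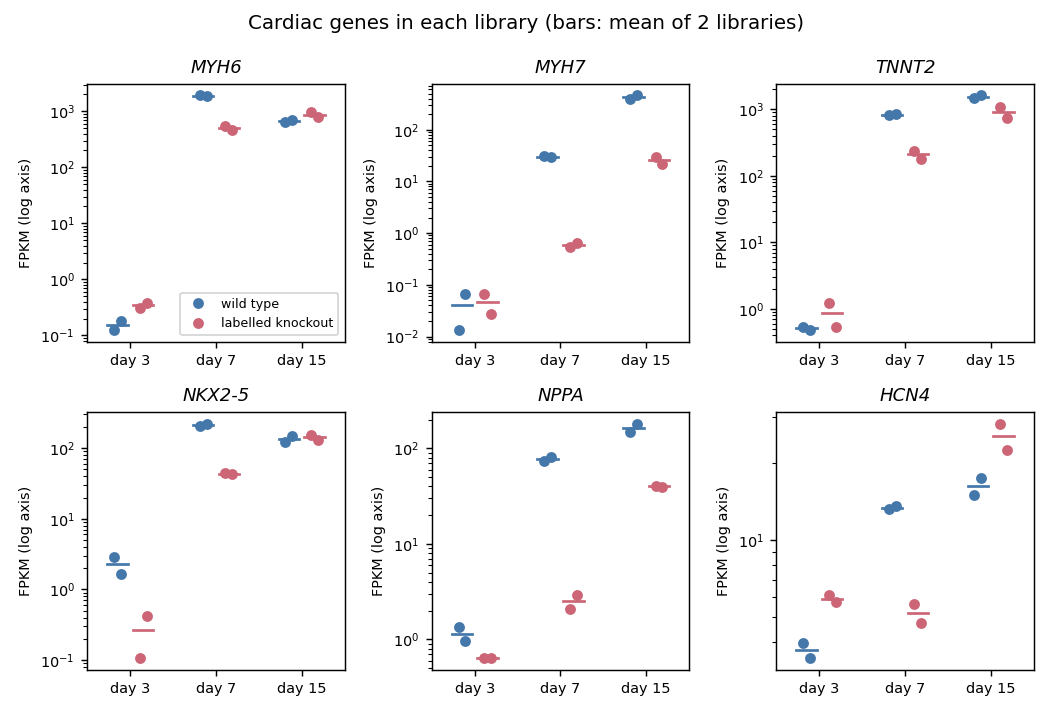
FPKM (vertical axis, log scale) of 6 cardiac genes in each of the 12 libraries by day, wild type in blue and labelled knockout in red, each point a library and each bar the mean of 2 libraries. At day 7 NPPA stands at 78.0 FPKM in the wild type and 2.49 FPKM in the libraries labelled knockout, and at day 15 at 164 and 39.9 FPKM.

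Gene lists named for other cell types were lower at day 7 too, though this does not show that those cells were fewer. Endothelial genes fell in 8 of 10 cases, also 8 adjusted over the list alone, with CDH5, vascular endothelial cadherin, lower by 1.77 (mean -0.98, adjusted p = 4.49e-04). Endoderm genes fell in 7 of 9 cases, also 7 adjusted over the list alone (mean -1.17, adjusted p = 6.76e-05), and epithelial genes in 11 of 12, or 12 adjusted over the list alone (mean -1.23, adjusted p = 1.23e-07, and 0.0635 with an estimated correlation), KRT19, a keratin, among them by 2.17. Smooth muscle genes fell in 6 of 9 cases and rose in 1, the same counts adjusted over the list alone, with ACTA2, smooth muscle actin, at 47.4 ± 4.43 against 557 ± 4.33 FPKM (-3.53, SE 0.22, list adjusted p = 0.00278, and 0.168 with an estimated correlation). Matrix genes fell in 5 of 9 cases and rose in 1, the same counts adjusted over the list alone, with FN1 lower by 1.51 (adjusted p = 0.049, and 0.273 with an estimated correlation). Only 3 of the 13 fixed skeletal muscle genes were measured. Of these 2 fell, also 2 adjusted over the list alone (adjusted p = 0.0179, and 0.195 with an estimated correlation). They were CKM, also in the working chamber list, and ACTA1, skeletal actin. BMP pathway genes fell in 12 of 18 cases and rose in 1, the same counts adjusted over the list alone, with BAMBI, a pseudoreceptor, lower by 1.86 and GREM1, a BMP antagonist, higher by 2.35 (adjusted p = 9.69e-06). NODAL and activin pathway genes fell in 6 of 9 cases and rose in 1, or 7 and 1 adjusted over the list alone (adjusted p = 3.61e-04), NODAL by 2.73 and LEFTY2 by 2.77. CDK inhibitors fell in 3 of 4 cases, also 3 adjusted over the list alone, with CDKN1A lower by 3.18 and CDKN1C by 1.94 (adjusted p = 0.00148, and 0.0876 with an estimated correlation). Mesendoderm genes fell in 6 of 11 cases and rose in 1, or 8 and 1 adjusted over the list alone (adjusted p = 0.00278, and 0.195 with an estimated correlation), and cardiac mesoderm genes fell in 10 of 13, also 10 adjusted over the list alone (adjusted p = 3.31e-06, and 0.0659 with an estimated correlation). MESP1 was under 1 FPKM in both genotypes and did not pass.

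Single genes of neural character and the cell cycle list were higher at day 7. SOX21 (chromosome 13, 94709622 to 94712399) stood at 37.0 ± 1.84 against 0.736 ± 0.2 FPKM (4.46, SE 0.18, adjusted p = 2.05e-07), PAX3, a paired-box factor of dorsal neural tube, neural crest and somites, at 25.8 ± 1.11 against 0.273 ± 0.0969 FPKM (4.40, SE 0.18), and POU3F1, a POU factor of neural progenitors, at 24.9 ± 1.85 against 0.609 ± 0.0906 FPKM (4.01). VGF, a neuropeptide precursor, rose by 3.81 and MAP2 by 3.66. The neural list had 3 higher members of 7 and none lower, the same counts adjusted over the list alone, with SOX2 at 155 ± 2.9 against 21.1 ± 0.157 FPKM, and did not pass as a set (mean 0.76, adjusted p = 0.122). Pluripotency genes rose in 6 of 8 cases and fell in 1, the same counts adjusted over the list alone, SALL4 by 1.33 (adjusted p = 0.0133, and 0.172 with an estimated correlation). TDGF1, a NODAL co-receptor, was the member that fell (-2.06). Cell cycle genes rose in 13 of 18 cases and fell in 1, the same counts adjusted over the list alone, with a mean of 0.56 (adjusted p = 3.72e-04), among them CCNB2, a mitotic cyclin, by 0.99. NOTCH pathway genes rose in 8 of 14 cases and fell in 2, or 9 and 2 adjusted over the list alone (adjusted p = 0.0488, and 0.273 with an estimated correlation), JAG1, a ligand, by 1.59.

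Energy metabolism differed in the same libraries. Glycolysis and hypoxia genes fell in 13 of 14 cases, also 13 adjusted over the list alone, with a mean of -1.10 (adjusted p = 2.84e-08), ENO1, enolase, at 807 ± 20.5 against 1870 ± 51.1 FPKM and LDHA, lactate dehydrogenase, at 576 ± 59.3 against 1210 ± 5.79 FPKM. All 11 mitochondrially encoded transcripts rose, also 11 adjusted over the list alone, with a mean of 1.41 (adjusted p = 2.4e-08), MT-ND1, a subunit of respiratory complex I, from 1050 ± 40.3 to 3360 ± 13.6 FPKM. Fatty acid oxidation genes fell in 6 of 11 cases and rose in 2, the same counts adjusted over the list alone, with FABP3, a fatty acid carrier of heart muscle, lower by 3.14 (adjusted p = 0.0488, and 0.132 with an estimated correlation).

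**Figure D3:**
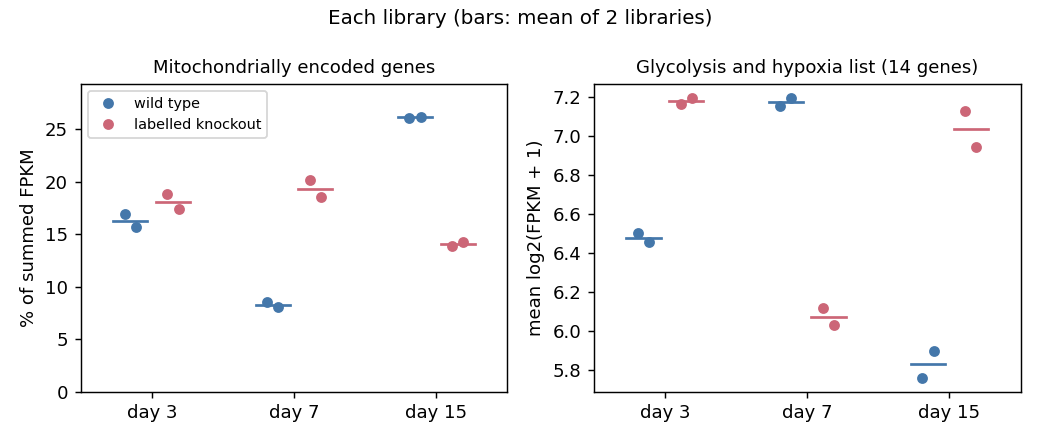
The left panel gives the share of summed FPKM held by mitochondrially encoded genes (%, from 0) and the right panel the mean log2(FPKM + 1) of the 14 measured glycolysis and hypoxia genes, in each of the 12 libraries by day, wild type in blue and labelled knockout in red, with bars at the mean of 2 libraries. At day 7 the share is 8.5% and 8.1% in the wild type and 20.2% and 18.5% in the libraries labelled knockout, and at day 15 it is 26.1% and 26.2% against 13.9% and 14.3%.

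At day 7, 6852 of 16295 genes changed, 3602 higher and 3250 lower, and 2420 changed at least 2-fold. Scaled to the sum of nuclear genes, 68.1% of the changed genes were higher in place of 52.6%, and the median change of all genes moved from 0.06 to 0.22. With median-ratio rescaling 45.1% were higher, with a median change of -0.02. Without wild-type replicate 2 the count was 4498.

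At day 15, when the wild-type libraries carried most MYH7, contractile genes were still lower in the libraries labelled knockout. MYH7 stood at 25.9 ± 5.68 against 429 ± 47.1 FPKM (-4.01, SE 0.17, adjusted p = 3.92e-07), DES, the muscle intermediate filament, at 3.87 ± 0.0982 against 71.8 ± 9.18 FPKM (-3.90, SE 0.20), and ANKRD1 (chromosome 10, 90912096 to 90921276), a cardiac ankyrin-repeat protein, at 58.6 ± 13.1 against 851 ± 62.9 FPKM (-3.85, SE 0.15). TNNI3, cardiac troponin I, fell by 2.23. Sarcomere genes fell in 13 of 16 cases and rose in 1, or 14 and 1 adjusted over the list alone, with a mean of -1.41 (camera adjusted p = 3.11e-08, and 0.0326 with an estimated correlation). The member that rose was MYH6 (0.38, SE 0.13, adjusted p = 0.0392), and this call ended without wild-type replicate 1 (0.31), wild-type replicate 2 (0.46) or labelled knockout replicate 1 (0.24), and with a pseudocount of 0.1, without the trend or on that day alone. TNNT2 stood at 902 ± 238 against 1550 ± 101 FPKM (-0.80, adjusted p = 0.0125), a call that ended without wild-type replicate 2 (-0.74) or labelled knockout replicate 2 (-0.53), and with a pseudocount of 0.1.

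NPPA remained lower at day 15, at 39.9 ± 0.333 against 164 ± 24.4 FPKM (adjusted p = 2.15e-05), and ISL1 and TBX3 fell by 0.94 and 0.95. HCN4 was higher by 0.61 (25.3 ± 4.27 against 16.2 ± 1.75 FPKM, adjusted p = 0.0155), which ended without wild-type replicate 1 (0.50) or labelled knockout replicate 1 (0.44), and in a fit on that day alone. NKX2-5 changed by 0.07 (SE 0.19, adjusted p = 0.792), NODAL by -0.35 and LEFTY2 by -0.28, and none of these passed. TBX5, a T-box factor of the first heart field, rose from 2.46 ± 0.228 to 21.9 ± 6.75 FPKM, IRX4, a ventricular homeobox factor, by 2.41 and CACNA1G, a T-type calcium channel, by 2.62. As sets, the cardiac transcription factors (4 lower and 2 higher of 12), the sinoatrial node list (7 higher and 3 lower of 14), the atrial list (6 higher and 3 lower of 10), the ventricular list (3 higher and 2 lower of 7) and the calcium handling list (5 lower and 2 higher of 11) did not pass, with adjusted p of 0.372, 0.331, 0.167, 0.843 and 0.244. Adjusted over the list alone the counts were the same except for calcium handling, with 5 lower and 3 higher. The ventricular mean was -0.16 with a median of 0.13 and an upward test.

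Other muscle and signalling groups differed at day 15. Smooth muscle genes fell in 6 of 9 cases, also 6 adjusted over the list alone, TAGLN, a calponin-family actin binder, from 1160 ± 81.6 to 213 ± 14.4 FPKM (-2.45, list mean -1.25, adjusted p = 4.5e-05, and 0.153 with an estimated correlation). S100A10 (chromosome 1, 151982915 to 151994390), a partner of annexin, stood at 33.7 ± 0.135 against 435 ± 8.94 FPKM (-3.65), and KRT7 (chromosome 12, 52232520 to 52252186), a keratin, at 6.19 ± 2.22 against 125 ± 2.37 FPKM (-4.16, SE 0.27). Epithelial genes, with 3 higher and 3 lower of 12, the same counts adjusted over the list alone, did not pass (adjusted p = 0.843, with a mean of -0.24, a median of 0.22 and an upward test). Skeletal muscle genes fell in 3 of 3 cases, also 3 adjusted over the list alone, with ACTA1 lower by 2.96 (adjusted p = 0.00315, and 0.202 with an estimated correlation). Only these 3 of the 13 fixed genes were measured, and CKM among them is also in the working chamber list. The call of MYH3 (-0.98) ended without labelled knockout replicate 2 (-0.78) or wild-type replicate 2 (-0.66). NODAL and activin pathway genes fell in 4 of 9 cases, also 4 adjusted over the list alone, with INHBA lower by 3.26 (adjusted p = 0.00388, and 0.139 with an estimated correlation). NOTCH pathway genes rose in 9 of 14 cases, or 11 higher and 1 lower adjusted over the list alone, JAG1 and NOTCH1, a receptor, each by 1.69 (adjusted p = 4.12e-04, and 0.171 with an estimated correlation). WNT pathway genes rose in 8 of 16 cases and fell in 3, or 11 and 4 adjusted over the list alone, with AXIN2, a transcriptional target of WNT signalling, higher by 1.90 (adjusted p = 0.027, and 0.381 with an estimated correlation). Outside that list WNT3A, a canonical ligand, rose from 0.687 ± 0.352 to 18.7 ± 2.11 FPKM (3.56, SE 0.19). CLDN10 (chromosome 13, 95433604 to 95579759), a tight-junction protein, showed the largest rise among the genes named by rule, at 29.1 ± 3.0 against 1.05 ± 0.166 FPKM (3.87, SE 0.16), and CRABP1, a retinoic acid binding protein, rose by 3.71.

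Progenitor, endothelial and neural markers at day 15 were measured beside the muscle genes. LIN28A, an RNA-binding protein of pluripotent and progenitor cells, stood at 349 ± 23.3 against 62.5 ± 2.55 FPKM (2.46, SE 0.10), and SOX2 at 47.7 ± 11.2 against 7.79 ± 1.5 FPKM (2.46). The pluripotency list, with 4 higher and 1 lower of 8, did not pass (adjusted p = 0.11), nor did the neural list, with 4 higher and none lower of 7 (adjusted p = 0.0776), or the endothelial list, with 5 higher and 1 lower of 10 (adjusted p = 0.11). Adjusted over the list alone these counts were 4 and 1, 5 and 1, and 6 and 1. CDH5, lower at day 7, was higher by 1.25 at day 15.

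The glycolysis list and the mitochondrially encoded transcripts stood the other way at day 15 than at day 7. Glycolysis and hypoxia genes rose in 10 of 14 cases, or 11 adjusted over the list alone, with a mean of 1.21, SLC2A1, a glucose transporter, from 78.0 ± 4.06 to 463 ± 99.1 FPKM and HK2 by 2.06 (adjusted p = 3.51e-07, and 0.139 with an estimated correlation). All 11 mitochondrially encoded transcripts fell, also 11 adjusted over the list alone, with a mean of -1.23, MT-CO2, a subunit of cytochrome oxidase, from 7160 ± 216 to 2410 ± 25.7 FPKM (adjusted p = 4.25e-09, and 0.139 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 11 cases, also 5 adjusted over the list alone, FABP3 by 2.34 (adjusted p = 0.00691, and 0.139 with an estimated correlation). At day 15, 5723 genes changed, 3080 higher and 2643 lower, and 1891 changed at least 2-fold. The count was 3803 without wild-type replicate 2, and 3657 in a fit on the libraries of that day alone.

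**Figure D4:**
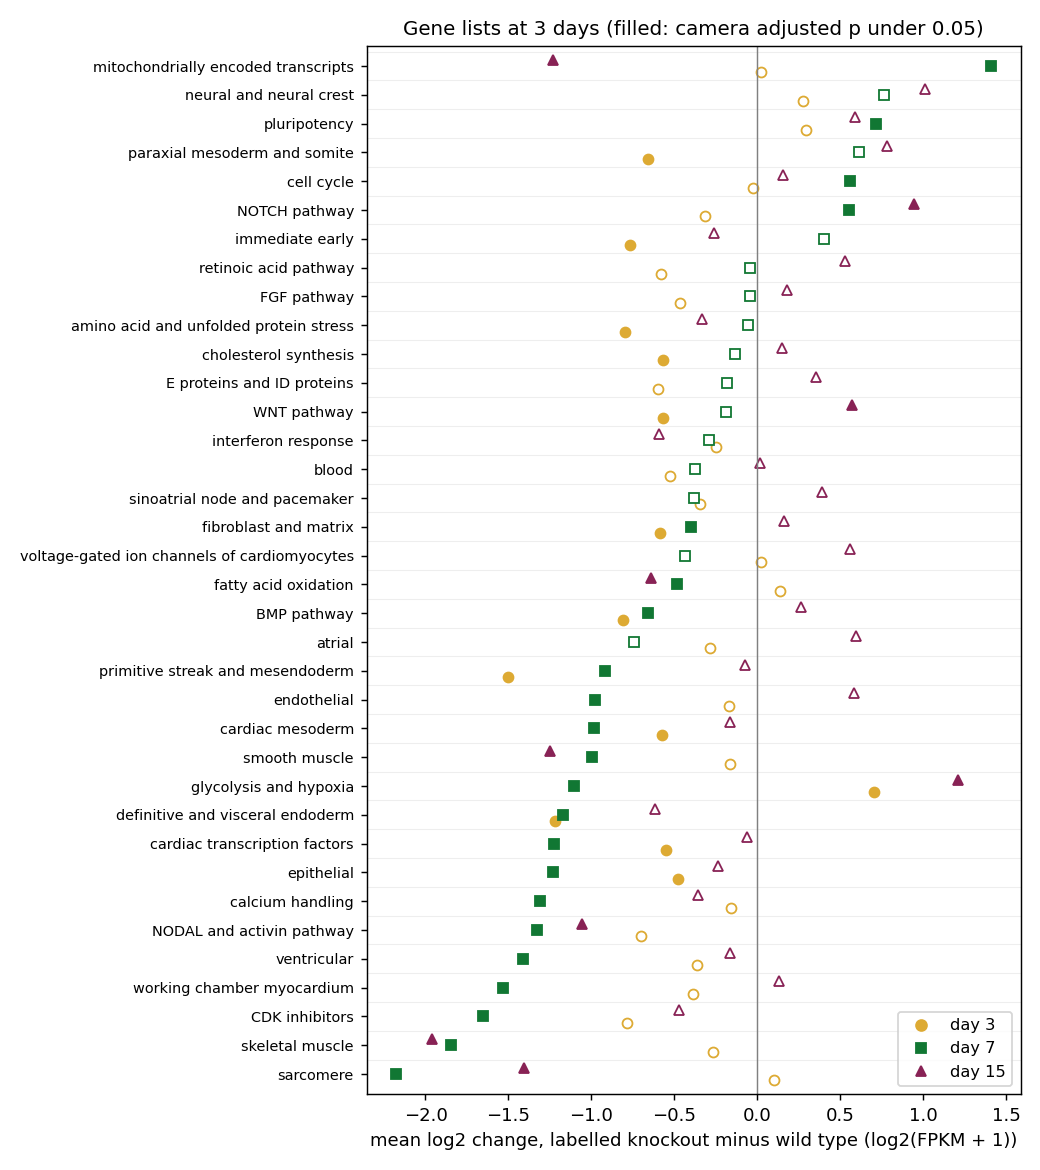
Mean log2 change, labelled knockout minus wild type on the log2(FPKM + 1) scale, of the gene lists at days 3, 7 and 15, with filled points for lists past the camera test at an adjusted p of 0.05. The sarcomere list stands at 0.10, -2.18 and -1.41, and the glycolysis and hypoxia list at 0.70, -1.10 and 1.21.

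Whether the same genes differed at more than 1 day was asked by overlap, and the comparisons share no library. They do share each gene's estimate of the spread, so a gene with a small estimate passes more easily at every day. The counts for independent lists leave this out. Higher at both days 3 and 7 were 733 genes, where independent lists give 342.6, and lower at both were 1107, where they give 458.5, while 368 changed in opposite directions against 817.3. Between days 7 and 15 the counts were 993 higher (680.8 for independent lists), 1033 lower (527.1) and 886 opposite (1198.5). Between days 3 and 15 they were 522 higher (293), 658 lower (372.9) and 589 opposite (686). Among genes changed at least 2-fold at both days, opposite changes numbered 50 (79.6 for independent lists) at days 3 and 7. They numbered 128 (139.4) at days 7 and 15, and 76 (62.7) at days 3 and 15, so the deficit was not general. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.368, 0.241 and 0.151. Over all 3 days 294 genes were higher and 438 lower.

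The differences between days were tested as interactions. From day 3 to day 7 the sarcomere list rose by 2.28 less in the libraries labelled knockout than in the wild type. Of its members 14 of 16 were past the test, also 14 adjusted over the list alone (adjusted p = 4.27e-16, and 0.00479 with an estimated correlation). MYH7 differed by -4.30 (SE 0.24), FABP3 by -4.51, NPPA by -4.13, TNNT2 by -2.29 and HCN4 by -1.77. PAX3 differed by 4.54 (SE 0.26) and SP8, a zinc finger factor of neural and limb patterning, by 3.98. At day 3 MYH7 (0.0465 against 0.0405 FPKM), TNNT2, NPPA, PAX3 and part of the sarcomere list were near the floor in both genotypes. A fall at day 3 could hardly show there on the log2(FPKM + 1) scale, so these interactions largely repeat the change at day 7. The glycolysis and hypoxia list differed by -1.80, with 13 of 14 members lower, also 13 adjusted over the list alone (adjusted p = 4.66e-15, and 0.0403 with an estimated correlation). In all 3285 genes differed, 1835 higher and 1450 lower, and leaving out a wild-type library gave 1962 and 2066 (day 3, replicates 1 and 2) and 1945 and 1920 (day 7, replicates 1 and 2).

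From day 7 to day 15 the effect moved up for several cardiac genes. NKX2-5 moved by 2.34 (SE 0.27), MYH6 by 2.27, NPPA by 2.5 and TNNT2 by 1.19 relative to the wild type. MB, myoglobin, moved by 5.02 (SE 0.33), from 8.51 ± 0.211 against 59.8 ± 4.16 FPKM at day 7 to 33.3 ± 8.87 against 5.62 ± 0.191 FPKM at day 15. Working chamber genes moved up in 9 of 10 cases, also 9 adjusted over the list alone (mean 1.66, adjusted p = 5.54e-06, and 0.0565 with an estimated correlation). Endothelial genes moved up in 7 of 10 cases, also 7 adjusted over the list alone (mean 1.56, adjusted p = 2.02e-04). All 14 glycolysis and hypoxia genes moved up, with a mean of 2.31 (adjusted p = 5.79e-13), and all 11 mitochondrially encoded transcripts moved down, with a mean of -2.64 (adjusted p = 3.09e-13), the same counts adjusted over the list alone. In all 5173 genes differed, 2698 higher and 2475 lower.

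Within the libraries labelled knockout, cardiac genes rose over the course as well. MYH6 rose by 8.56 between days 3 and 7, TNNT2 by 6.82 and NKX2-5 by 5.15, and the sarcomere list rose in 14 of 16 cases, or 16 adjusted over the list alone (mean 3.65, adjusted p = 5.35e-16). Between days 7 and 15 MYH7 rose from 0.593 ± 0.0596 to 25.9 ± 5.68 FPKM (4.06, SE 0.17), NPPA by 3.56 and HCN4 by 2.08, while SOX21 fell by 3.48 and POU3F1 by 3.52. Sarcomere genes rose in 15 of 16 cases, or 15 higher and 1 lower adjusted over the list alone (mean 1.63, adjusted p = 2.17e-10), and cell cycle genes fell in 12 of 18, or 14 adjusted over the list alone (mean -0.97, adjusted p = 2.23e-08). The counts of changed genes were 4668 (2811 higher and 1857 lower) and 4628 (2168 higher and 2460 lower). They were 2947 without labelled knockout replicate 1 of day 3, and 2902 without replicate 1 of day 7, and the second was 2084 in a fit on its own groups alone.

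The differences at day 7 were set against the wild-type course from day 3 to day 15, which shares no library with them. Over the 9635 genes that changed along that course, Pearson's r across genes was -0.179 and Spearman's rho -0.107. Of the 4764 genes that rose along the course 52.4% had a negative change at day 7, and of the 4871 that fell 53.5% had a positive one. Over all 16295 genes r was -0.143, with a negative change in 47.9% of the 8292 with a positive course and a positive one in 54.7% of the 8003 others.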

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

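The tests on the share of cardiomyocytes and on dilution by fewer cardiomyocytes were chosen only after the result was seen, as was the scaling to nuclear genes as a setting.

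The effect of the label differed between days 3 and 7 by an interaction test for 3285 genes. Among the genes named by rule, those with a higher effect at day 7 were PAX3 (4.54), TPBG (4.38), SP8 (3.98), EGR1 (3.96) and VGF (3.95), and those with a lower effect were FABP3 (-4.51), MYH7 (-4.30), NPPA (-4.13), MASP1 (-4.01), TNNT2 (-2.29), MYH6 (-2.12) and HCN4 (-1.77). PAX3, MYH7, NPPA, MASP1, TNNT2, MYH6 and part of the sarcomere list were near the floor in both genotypes at day 3. Their interactions therefore largely repeat the change at day 7. Of 37 lists tested with camera 9 moved up and 13 down, and the calls that held with an estimated correlation were sarcomere (-2.28), calcium handling (-1.15) and glycolysis and hypoxia (-1.80). GPR157 (-4.98, SE 1.31), NODAL (-1.04) and NKX2-5 (-0.90) also differed, each with calls that single libraries ended. For GPR157 the change was -4.81 and -5.16 without day 3 wild-type replicates 1 and 2, -5.02 and -4.94 without day 7 labelled knockout replicates 1 and 2, and -4.07 without day 7 wild-type replicate 2, where each call ended, and -3.11 without day 3 labelled knockout replicate 1, where it held. For NODAL it was -0.87 without day 3 labelled knockout replicate 2, -0.97 and -1.11 without day 3 wild-type replicates 1 and 2, -0.93 and -1.15 without day 7 labelled knockout replicates 1 and 2, and -0.90 and -1.18 without day 7 wild-type replicates 1 and 2. For NKX2-5 it was -0.71 without day 3 labelled knockout replicate 2, -0.62 without day 3 wild-type replicate 2, -0.93 and -0.86 without day 7 labelled knockout replicates 1 and 2, and -0.96 and -0.84 without day 7 wild-type replicates 1 and 2, and its call also ended without the trend and in a fit on the 4 groups alone. With a pseudocount of 0.1 the NKX2-5 change turned to 0.527 and was not called.

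Between days 7 and 15 the effect differed for 5173 genes by the same kind of test. Higher at day 15 were MB (5.02), CAPN3 (4.25), FAM19A4 (4.14), RIPPLY3 (4.11), NPPA (2.5), LEFTY2 (2.49), NODAL (2.38), NKX2-5 (2.34), MYH6 (2.27), HCN4 (1.83) and TNNT2 (1.19). Lower were POU4F1 (-4.53), CHAC1 (-3.74), CPT1B (-3.57) and MT-ND4L (-3.44). Of the 37 lists 17 moved up and 3 down, and the calls that held with an estimated correlation were endothelial (1.56), BMP pathway (0.92), glycolysis and hypoxia (2.31) and mitochondrially encoded transcripts (-2.64). MKKS (-4.77, SE 1.66) and ISL1 (0.58) differed with calls that single libraries ended. For MKKS the change was -3.42 without day 15 labelled knockout replicate 1, -4.89 and -4.64 without day 15 wild-type replicates 1 and 2, -2.82 without day 7 labelled knockout replicate 2, and -4.91 and -4.62 without day 7 wild-type replicates 1 and 2, and its call also ended with median-ratio rescaling, no filter, a pseudocount of 0.1, without the trend and in a fit on the 4 groups alone. For ISL1 it was 0.60 and 0.56 without day 15 wild-type replicates 1 and 2, 0.54 without day 7 labelled knockout replicate 2, and 0.59 and 0.57 without day 7 wild-type replicates 1 and 2, and its call also ended when scaled to nuclear genes.

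The first pattern weighed is that glycolysis and hypoxia genes were lower at day 7 and higher at day 15, with mitochondrially encoded transcripts the other way. Scaling to nuclear genes left the glycolysis and hypoxia list at -0.90 (camera adjusted p = 4.04e-09) and 1.22 (camera adjusted p = 4.03e-07). The first mean argues against scaling as the whole cause of the fall at day 7. Camera compares a list with other genes, so a scale factor hardly changes its p. At day 15 this scaling moved the median change of all genes only from 0.033 to 0.037, so it tested little there. It drops the mitochondrially encoded genes, so their part of the pattern was not tested. A smaller share of cardiomyocytes stays open at both days. Mitochondrially encoded transcripts had means of 1.41 at day 7 and -1.23 at day 15 beside a lower sarcomere list, but from day 3 to day 7 in the wild type they moved by -1.325 (adjusted p = 2.16e-07, and 0.0632 with an estimated correlation) while the sarcomere list rose by 5.93, so their sign does not tell the share. The oxygen or feeding state of the cultures at harvest stays open, since 24 further hypoxia-inducible genes had means of -0.70 (adjusted p = 1.29e-05, and 0.0543 with an estimated correlation) and 0.70 (adjusted p = 1.44e-05, and 0.107 with an estimated correlation). An effect of the genotype on metabolism is open as well and was not tested.

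The second pattern is that several neural genes were higher at day 7, although the fixed neural list did not pass. Dilution by fewer cardiomyocytes alone raises the markers of every other cell type alike. The endothelial (-0.98), endoderm (-1.17) and epithelial (-1.23) list means fell instead, but this counts only where their genes mark cells other than cardiomyocytes. In the wild type KRT8 (979 to 3810 FPKM) and APOA1 (0.529 to 33.8 FPKM) rose from day 3 to day 7 as sarcomere genes did. EPCAM (258 to 234 FPKM) and CDH1 (260 to 131 FPKM) did not. Genes expressed in cardiomyocytes would fall with fewer of them, so the test does not decide. The list means also cannot exclude a dilution in which those cell types fell along with the cardiomyocytes. Mesendoderm and endoderm genes were already lower at day 3. A larger share of neural-like cells stays open: 17 further neural plate genes had a mean of 1.07 (adjusted p = 1.71e-04, and 0.039 with an estimated correlation), with 10 higher and 2 lower. A difference in the culture of the cells labelled knockout was not tested and stays open.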

How the results depend on the processing

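The call of TCF3 at day 15 kept its direction under every alternative run on it. Limma without trend, median-ratio rescaling, no filter, a filter at 5 FPKM and a pseudocount of 0.1 left TCF3 at days 3, 7 and 15 on its side of the threshold and the 9 counts of changed genes within 1.5 times. The list test counts, the overlaps and the correlation with the wild-type course were not run under these. Scaling to nuclear genes was chosen after seeing the data. It turned the sign of TCF3 at day 3, which was not called in either fit (-0.153, and 0.024 with adjusted p = 0.938), and moved TCF3 at day 7 to 0.569 (adjusted p = 0.0235, past the threshold). Fits on the compared groups alone put TCF3 at day 7 past the threshold (0.363, adjusted p = 0.0164), left TCF3 at day 15 short of it (0.66, adjusted p = 0.0774), and gave 3657 changed genes at day 15 and 2084 between days 7 and 15 in the libraries labelled knockout. These fits have fewer libraries. The pooled SD between replicates on the log2 scale was 0.323 in the libraries labelled knockout at day 15, against 0.208 to 0.267 in the other groups. The main fit shares its estimate of the spread over all groups, so its p-values for contrasts with that group may be too small. The cause was not tested further. With an estimated correlation 4, 11 and 1 of the gene list tests passed at days 3, 7 and 15. With fry, which compares a list with no other genes, 29, 33 and 29 passed at these days. Requiring a change of at least 1 left, by construction, overlaps of 144 higher and 192 lower genes (days 3 and 7), 220 and 214 (days 7 and 15), and 86 and 100 (days 3 and 15). The correlation with the wild-type course over all genes was -0.143, and the cause was not tested. Reversed were LEFTY2 (0.28 in the interaction of days 3 and 7, -1.656 with a pseudocount of 0.1, where it passed with adjusted p = 0.0116 after 0.465 in the main fit) and NKX2-5 in the same interaction (-0.897, and 0.527 with that pseudocount, adjusted p = 0.514), where a smaller pseudocount widens changes near 0 FPKM by construction. Leaving out 1 library assumes that the lone sample varies like the other groups. It gave 1990 to 2503 changed genes at day 3, 4498 to 5241 at day 7, 3803 to 5524 at day 15, 5069 to 5300 and 6381 to 6730 along the wild-type course, 2947 to 3284 and 2902 to 4897 along that of the libraries labelled knockout, and 1920 to 2558 and 3666 to 5608 in the interactions. For TCF3 it gave -0.287 to -0.019 at day 3, 0.331 to 0.395 at day 7 and 0.339 to 0.981 at day 15. Over the named genes, leaving out 1 library ended the call in 151 of 2334 cases and made a call in 8. The 2334 cases include genes not called in the main fit, where no call could end, so the share of calls lost is larger. Of the list means, scaling to nuclear genes moved 106 of 185 by more than the spread between replicates and a pseudocount of 0.1 moved 101 of 190, and no called list mean reversed.

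The replicate numbers are shared between groups, and nothing in the labels pairs the samples. Deviations of same-numbered libraries of the genotypes correlated at 0.037, 0.024 and -0.121 at days 3, 7 and 15. Within the wild type across days they correlated at 0.017 (days 3 and 7), 0.014 (days 7 and 15) and -0.035 (days 3 and 15), and within the libraries labelled knockout at 0.155, 0.206 and 0.103. Shared numbers across days in those libraries therefore stay open. With the replicate block the counts were 2947, 6117 and 4964 at days 3, 7 and 15, 7393 and 8832 along the wild-type course, 4984 and 5001 along that of the libraries labelled knockout, and 2276 and 4331 in the interactions. With the replicate block TCF3 was at -0.153 (adjusted p = 0.678), 0.363 (adjusted p = 0.231) and 0.66 (adjusted p = 0.0557), and the call at day 15 ended.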

Other observations

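The interferon list was chosen for this part only after the results were seen.

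Interferon response genes had 3 lower members of 10 at day 3, 4 lower and 1 higher at day 7, and 6 lower and 1 higher at day 15, or 4, 4 and 1, and 6 and 1 adjusted over the list alone, and did not pass as a set (adjusted p = 0.293, 0.167 and 0.0685). ISG15, a ubiquitin-like protein induced by interferon, stood at 16.1 ± 2.23 against 42.3 ± 1.28 FPKM at day 7 (-1.35) and at 8.7 ± 0.887 against 36.6 ± 7.87 FPKM at day 15 (-1.94). IFITM3, a membrane protein of antiviral defence, was lower by 1.14 at day 7 and by 0.75 at day 15, while BST2, tetherin, was higher by 3.54 at day 15.

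The median change per autosome ran from -0.14 (chromosome 20) to 0.05 (chromosome 15) at day 3, from -0.06 (chromosome 4) to 0.12 (chromosome 16) at day 7, and from -0.06 (chromosome 19) to 0.17 (chromosome 18) at day 15. Further hypoxia-inducible genes at day 3 were higher in 14 of 24 cases (mean 0.56, adjusted p = 3.88e-06, and 0.0766 with an estimated correlation). Further neural plate genes at day 3 were higher in 7 of 17 cases and lower in 2 and did not pass (mean 0.30, adjusted p = 0.0699, and 0.224 with an estimated correlation). Further neural plate genes at day 15 were higher in 12 of 17 cases (mean 1.26, adjusted p = 2.73e-06, and 0.0502 with an estimated correlation).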
